A study of Mus musculus with 20 samples.

How the data were processed

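The series compares left and right atrial appendages of 5 Pitx2c heterozygous and 5 wild-type littermate mice of the CD1 strain at 12 weeks of age, as 4 groups of 5 arrays. Per the labels' protocols, total RNA was extracted with RNeasy columns, checked on a Bioanalyser and turned into biotin-labelled cRNA with the TotalPrep kit for Illumina bead arrays. The scanner software, background correction and normalization are not given in the sources used here.

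The deposited table holds an intensity and a detection p-value column for 45281 probes on each array. The deposited intensities are on a linear scale, and between 33.7% and 33.9% of each array's values lie below 0, so a background had been subtracted. Sorted values of all 20 arrays are equal within 1.8 units, so the authors' values had been quantile-normalized although the table is called not normalized. The deposited detection p-value columns hold 1 minus the p, since bright probes stand at 1, and were turned around before use. A second deposited table, of processed values, is identical to the first, with a largest difference of 0. No array repeats another, and pairs of arrays correlate between 0.952 and 0.991.

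Gene names came from the platform annotation given with the values. Of the probes, 34885 have 1 symbol, 18 have several and 10378 have none here; probes with several or none were tested but not named. Hcn4 and Kcnn3 were detected on 0 arrays and not tested.

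Values were processed with limma 3.58.1 in R 4.3.3. The design, fixed before the data were examined, had assumed uncorrected intensities and applied neqc, that is normexp background correction from the detection p-values, an offset of 16, quantile normalization and log2. It was kept as written, although the intensities were already corrected and normalized; the closing section gives the results without this second correction. Differences on this log2 scale understate changes of dim probes because of the offset. Probes with a detection p under 0.05 on at least 5 arrays were tested, 20097 in all, 17137 of them with a gene name. A linear model with 4 group means was fitted to all 20 arrays with lmFit and eBayes, and p-values were adjusted by the Benjamini-Hochberg method over all tested probes, separately for each of 5 contrasts (genotype in LA, genotype in RA, side in each genotype, and the interaction). A probe was called at an adjusted p under 0.05. Where a probe was not detected on any array of a group, the fold is a lower bound against the lowest signal detected on those arrays, or against the probe's own signal if that is higher.

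The tested probe with the highest mean over all arrays stood for its gene. Of 37 gene lists written before the data were examined, covering cardiac functions, pathways and markers of cell types that atrial samples can hold, 36 had at least 3 tested genes. They were tested with camera at a preset correlation of 0.01, and beside it with camera at an estimated correlation and with fry, adjusted over the lists of a contrast. The lists called, or holding a called gene, are given in the results as far as the rule for named genes reaches. Named genes were chosen by a rule fixed beforehand: the 10 largest rises and 10 largest falls among called genes, filled to 5 by smallest p where few pass, members of the lists (up to 4 called and 2 not), 15 genes named in advance, and the 10 smallest p of the interaction. Of the list members the rule allows, the text prints a part. The unnamed probes called between the genotypes lie outside the rule and were named after their values were seen.

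The labels do not say that the replicate numbers pair the samples, and no pairing was used; the closing section gives a check of it. The labels name separate mice, and the number of arrays limits the precision. Arrays of the sides share animals in an unknown order. The tests were run on simulated data with the means and spreads of these probes and known changes added to some of them. Values were drawn independently for each probe and array, with the same spread on every array. Structure shared between probes and arrays of unequal quality were thus left out. For the genotype in LA, 83.6% of the 67 probes changed by a log2 value of 1 were recovered among 20097 probes run, and 29.9% of those changed by 0.5. For the genotype in RA these were 89.6% and 46.3%, for the sides in wild-type mice 88.1% and 34.3%, for the sides in heterozygous mice 79.1% and 23.9%, and for the interaction 59.7% and 7.46%. Each run changed 67 probes by 0.5, 67 by 1 and 66 by 2 and called between 115 and 161 probes, which loosens the adjustment. In the real data 1 or 2 probes were called for the genotype and the interaction, so the adjustment was stricter. The shares therefore overstate what could be recovered in those comparisons.

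Alternatives covered the background correction, normalization, source of values, filter on dim probes, probes per gene, variance model, arrays in the fit, replicate number as a block, Xist level as a covariate, and each array left out. Since the deposited tables are identical, the setting with the second table nearly repeats the one without further background correction. The tallies of settings below count both. Added after seeing the data were a plain floor with the same offset, covariates for Myl2, Adipoq and Upk3b, and fits without arrays with high Myl2, without arrays with Ucp1 signals and without 2 arrays whose probes disagreed within genes. Array position on chips was not analysed here.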

Results

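Total RNA from the atrial appendages of adult mice was measured on 20 Illumina bead arrays, with 45281 probes each. The mice were of the outbred CD1 strain and 12 weeks old, 5 of them heterozygous for Pitx2c and 5 wild-type littermates. Left and right atria of these mice made 4 groups of 5 arrays, named LA and RA here. Each array detected between 17316 and 19422 probes, and 20097 probes for 11154 named genes were tested. Xist, expressed from the inactive X chromosome, had a signal of 797.2 or more on every array, and of the Y-linked genes Eif2s3y and Kdm5d were detected on 0 arrays and Uty, by its best probe, on 19.

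The comparison of the atria of wild-type mice asks which genes differ between the sides of the normal adult heart. Bmp10, a growth factor of the atrial wall, was at least 58.9-fold higher in the right atrium (adjusted p = 3.6e-07). Cd207 was 45.6-fold, Cxcl13 39.5-fold and Vsig4 28.2-fold higher there. Cd207 and Cxcl13 were each detected on 1 of 5 wild-type LA arrays, so their folds depend on the offset. Over 27 other settings their log2 differences ran from -6.98 to -5.02 and from -7.64 to -5.15. Cd207 encodes langerin, Cxcl13 a chemokine that attracts B cells, and Vsig4 a complement receptor of macrophages. The hepcidin genes Hamp and Hamp2, Adm (adrenomedullin) and the adhesion gene Cntn2 were each between 9.76-fold and 13.7-fold higher in the right atrium, and Arpp21 at least 7.18-fold. In the left atrium, the lymphatic chemokine genes Ccl21a and Ccl21c were 17.8-fold and 13.3-fold higher and the unplaced gene LOC100041504 12.6-fold. Ddit4l, an inhibitor of mTOR signalling, was 11.3-fold higher on the left, with a log2 difference of 3.49 (SE 0.22, n = 5 arrays per group, adjusted p = 2.79e-09 by limma).

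Further genes that were higher in the left atrium of wild-type mice were Rprm, by at least 5.09-fold, the chemokine gene Cxcl14 (6.56-fold) and the kinase gene Mapk10 (5.99-fold). The exchanger gene Slc24a2 (5.51-fold), Phlda1 (5.43-fold) and the ferritin receptor gene Scara5 (5.36-fold) were also higher there. Probes of Ccl21a, Ccl21c and LOC100041504, and those of Hamp and Hamp2, target near-identical genes, so the members of each family cannot be separated. Over all tested probes, 660 passed an adjusted p of 0.05. Of these, 315 were higher in the left atrium, for 240 genes, and 345 in the right, for 260 genes. The difference was over 2-fold for 229 probes.

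By gene list, 5 of 9 sinoatrial node markers were higher in the right atrium of wild-type mice and none in the left (5 lower and 1 higher in the left when adjusted over the list alone). They included Vsnl1 with a log2 difference of -2.07, Shox2 with -1.55, Rgs6 with -1.54 and Tbx3 with -1.36. The list was called (camera, adjusted p = 1.62e-05), and adjusted p = 0.0144 with an estimated correlation. Of 30 genes of BMP, TGF-beta and Wnt signalling, 8 were higher in the right atrium and 1 in the left, or 10 and 1 when adjusted over the list alone. Beside Bmp10 these were, for example, the Wnt antagonists Sfrp2 (-1.98) and Frzb (-1.35) and the BMP target Id1 (-1.32). That list had an adjusted p of 2.9e-05, and adjusted p = 0.0334 with an estimated correlation.

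Macrophage markers showed 9 of 16 genes higher in the right atrium of wild-type mice and none in the left (12 and 1 when adjusted over the list alone), with Cx3cr1 at -1.69 and C1qb at -0.83. The list was called with an adjusted p of 7.4e-11, and adjusted p = 0.0677 with an estimated correlation. Among 23 cardiac transcription factors, 5 were higher in the right atrium (6 of them, and 1 in the left, when adjusted over the list alone), among them Hey1 (-1.41) and Irx3 (-1.14). The endothelial genes Vwf (-0.87) and Eng (-0.59) were higher in the right atrium, 2 of 20 on their list and 2 when adjusted over the list alone. Their lists were called (adjusted p = 0.00035 and 0.000988), with adjusted p = 0.173 and 0.0949 with an estimated correlation. All 44 tested genes of oxidative phosphorylation had positive differences, of median 0.12, yet 0 passed alone by either adjustment; the list had an adjusted p of 0.00016, and adjusted p = 0.174 with an estimated correlation.

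Mast cell and cell cycle lists were called lower in the left atrium of wild-type mice with an adjusted p of 0.0253 each, and adjusted p = 0.186 and 0.206 with an estimated correlation. Outside called lists, the calcium release channel gene Ryr3 was 6.56-fold higher in the right atrium and Camk2b 1.71-fold higher in the left. Fibroblast markers went both ways, 3 of 16 higher in the left, with Pi16 (3.47-fold) and Mfap4 (2.21-fold), and 2 higher in the right, Tcf21 (2.00-fold) and Dpep1 (1.89-fold), with the same counts when adjusted over the list alone. Of 10 skeletal muscle markers the fast troponin gene Tnni2 (4.79-fold) was higher in the left and Myl1 (1.30-fold) in the right (2 and 4 when adjusted over the list alone). Dpep1 and Myl1 each passed in 14 of 28 other settings, with adjusted p up to 0.248 and 0.216. Dbh, the enzyme that makes noradrenaline, was 6.55-fold higher in the right. Of 13 tested genes fixed beforehand for every comparison, Bmp10 and Shox2 passed. Shox2 passed in 18 of 27 other settings (adjusted p up to 0.418), and not without LA wild-type replicate 2, 3, 4 or 5 or RA wild-type replicate 4 or 5 (adjusted p between 0.0557 and 0.09). The other 11 (Nppa, Nppb, Sln, Myl7, Myl4, Tbx5, Nkx2-5, Gja1, Gja5, Kcnj3 and Xist) had log2 differences between -0.37 for Nppb and 0.36 for Kcnj3, with adjusted p of 0.525 or more. Mean levels of Nppa, Sln, Myl7 and Myl4 were 14.82 or more on the log2 scale in every group, near the highest signal on the arrays (38625.9), where differences can be compressed, so their values here and below do not speak against a difference.

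Myl2, the ventricular light chain, was 48.9-fold higher in the right atrium of wild-type mice (log2 difference -5.61, SE 1.18, adjusted p = 0.00789), and its deposited signal ran from 698.2 to 29382.7 in RA wild type and from 6.9 to 106 in LA wild type. Without RA wild-type replicate 2 the log2 difference of Myl2 was -4.77 (adjusted p = 0.0243), and over 26 other settings its adjusted p reached 0.0539. The left-right tests treat the arrays as independent although both atria came from the same mice, since the labels do not say which arrays share a mouse. With log2 levels of Myl2, Adipoq and Upk3b as covariates the count was 351 probes, and with array weights 1001.

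In the atria of heterozygous mice the comparison of the sides asks whether the same genes differ when one copy of Pitx2c is lost. Bmp10 was 31.7-fold, Cd207 17.9-fold, Cxcl13 13.0-fold and Vsig4 8.60-fold higher in the right atrium. The fold of Bmp10 depends on the offset and on LA replicate 2, the 1 of 5 heterozygous LA arrays that detected it. Its log2 difference ran from -8.21 to -4.60 over 27 other settings. Hamp2, Hamp and Adm were between 9.64-fold and 12.1-fold higher there, the ion transport regulator gene Fxyd3 7.39-fold, Dbh 6.00-fold and the prostaglandin D synthase gene Ptgds 5.39-fold. In the left atrium, Ccl21a was 6.84-fold, Scara5 6.29-fold, Phlda1 5.56-fold, Timp4 5.51-fold and Ddit4l 5.46-fold higher. LOC100041504, Ccl21c, Slc24a2, 2310002L09Rik and Dlgap1 followed with differences between 3.71-fold and 5.34-fold.

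In total 524 probes passed in heterozygous mice, 249 of them higher in the left atrium (191 genes) and 275 in the right (209 genes). Of these calls, 157 left-higher and 195 right-higher probes were also called in wild-type mice, where independent lists of these lengths would share 3.90 and 4.72. No probe was called in opposite directions. The log2 differences of the 2 comparisons come from different arrays and different mice. Their calls share 1 estimate of each probe's spread, so the lists are not independent and the numbers for independent lists are only a rough guide. Across all tested probes, which are not independent replicates, the log2 differences had a Pearson correlation of 0.656 and a Spearman correlation of 0.379. Of the 832 probes called in either genotype, 825 had the same sign in both.

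**Figure D1:**
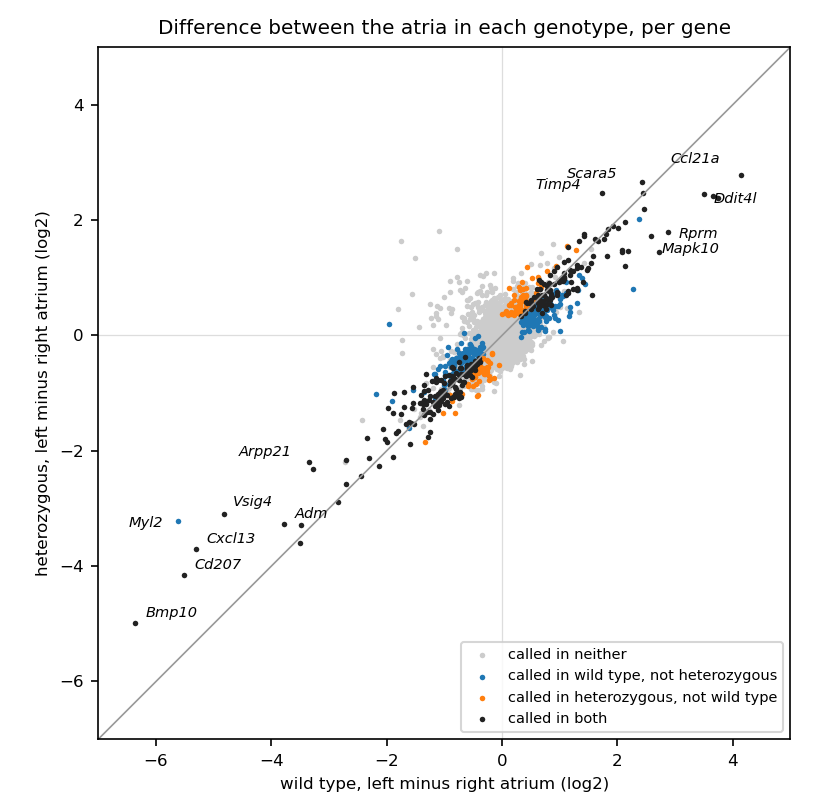
Log2 difference between left and right atrium in wild-type mice (x axis) and in heterozygous mice (y axis), 1 point per gene, 5 arrays per group, coloured by the comparison in which the gene's brightest tested probe passed an adjusted p of 0.05; the grey line marks equal values. Bmp10, detected on 0 wild-type LA arrays, is at least 58.9-fold higher in the right atrium of wild-type mice and lies farthest down; Ccl21a lies farthest right at 4.15 and 2.77.

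Sinoatrial node markers of heterozygous mice had 4 of 9 genes higher in the right atrium (5 when adjusted over the list alone), with Vsnl1 at -1.63, Rgs6 at -1.17, Tbx3 at -1.13 and the calcium channel gene Cacna1g at -1.01. The list was called with an adjusted p of 1e-04, and adjusted p = 0.0291 with an estimated correlation. BMP, TGF-beta and Wnt genes had 8 of 30 higher in the right atrium (10 when adjusted over the list alone, with 1 in the left), among them Sfrp2 (-1.26), Id1 (-1.19) and Id3 (-1.07); the adjusted p was 0.00179, and adjusted p = 0.175 with an estimated correlation. Macrophage markers went both ways: 2 of 16 were higher in the right atrium, Cx3cr1 (-0.99) among them, while Mrc1 was higher in the left by 0.59 (8 and 1 when adjusted over the list alone). That list was called lower in the left atrium (adjusted p = 1e-04), with adjusted p = 0.491 with an estimated correlation.

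Extracellular matrix genes of heterozygous mice had 7 of 35 higher in the left atrium (7 when adjusted over the list alone), including the crosslinking enzyme gene Lox (1.18) and Col8a1 (0.93), with an adjusted p of 0.000725, and adjusted p = 0.531 with an estimated correlation. Lists for smooth muscle, fatty acid oxidation, adipocytes, Schwann cells and oxidative phosphorylation were also called higher in the left atrium, and those for epicardium, skeletal muscle, cell cycle and ribosomal proteins lower. For these 9 lists the adjusted p lay between 0.00724 and 0.0452, and with an estimated correlation adjusted p = 0.239 or more. Among ion channel genes, Kcne1 (-1.84) was higher in the right atrium and Scn4b (1.48) in the left. Scn4b passed in 15 of 27 other settings (adjusted p up to 0.352). Of the list members named for heterozygous mice, Sfrp2 passed in 14 of 28 other settings (up to 0.467). Cx3cr1 and Col8a1 passed in 17 of 28 each (up to 0.792 and 0.294). Of the 13 fixed genes Bmp10 passed, and the others lay between -0.94 for Shox2 and 0.51 for Tbx5. The count was 250 probes without the 4 heterozygous arrays that had a Ucp1 signal over 100, which leaves 2 LA and 4 RA arrays, and 322 in a fit of the heterozygous arrays alone. It was 207 with Myl2, Adipoq and Upk3b levels as covariates.

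The left atria of heterozygous and wild-type mice were compared to find genes that depend on the genotype on that side. One gene passed the threshold. Cxcl13 was 3.42-fold higher in LA of heterozygous mice, with a log2 difference of 1.78 (SE 0.25, n = 5 arrays per group, adjusted p = 0.0159 by limma), and its deposited signal lay between 56.5 and 97.2 in heterozygous and between 2.8 and 22.5 in wild-type LA. Cxcl13 was detected on 1 of 5 wild-type LA arrays, so its fold depends on the offset, with log2 differences from 1.57 to 3.85 over 27 other settings. In RA it lay between 584.1 and 1935 across both genotypes. No probe passed as lower, and 937 of 20097 probes had an unadjusted p under 0.05, where 1004.85 would be counted with no difference at all.

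Other genes with the smallest p in the left atrium did not pass. Arpp21, detected on 0 wild-type LA arrays, was at least 1.42-fold higher (adjusted p = 0.115). Vsig4 had a log2 difference of 1.63 (SE 0.31), Mapk10 of -0.95 (SE 0.18), Rprm of -0.86 (SE 0.16), Capn6 of -0.68 and Lonrf3 of -0.63, each with an adjusted p of 0.115. Cdh22 had -0.83 (adjusted p = 0.332), Cd207 1.35 (0.456) and the catalase gene Cat 0.67 (0.698). The 13 tested fixed genes did not pass either and lay between -0.29 for Kcnj3 and 0.65 for Shox2. A second Arpp21 probe had a difference of 0.11 (SE 0.19, adjusted p = 1). That probe was detected on 0 heterozygous and 1 wild-type LA arrays, so its value there does not speak against a change. In other settings Arpp21 passed in 5 of 27 (adjusted p down to 9.14e-06 without further background correction; 0.0414 without LA heterozygous replicate 5), Vsig4 in 2 (0.0465 without LA heterozygous replicate 1), Mapk10 in 2 (0.0387 without LA wild-type replicate 2) and Capn6 in 1.

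**Figure D2:**
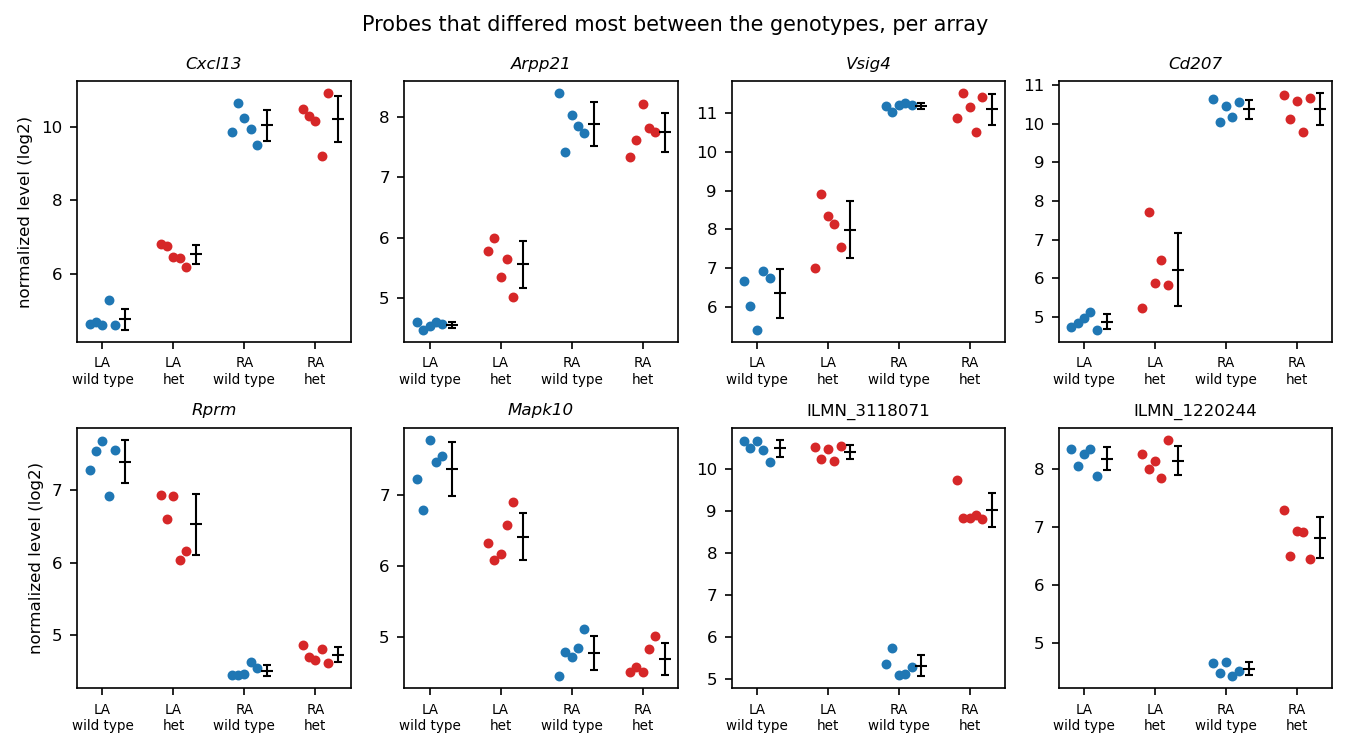
Normalized log2 level (y axis) of 6 genes and 2 probes without a gene name in each of the 20 arrays, by atrium and genotype; points are arrays, bars the mean ± SD of 5 arrays, and y axes differ between panels and do not start at 0. Cxcl13 averaged 1.78 higher in heterozygous than in wild-type LA, and ILMN_3118071 averaged 3.71 higher in heterozygous than in wild-type RA.

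Of 36 gene lists tested, 6 were called in the left atrium, while 0 of their members passed alone. All 12 adipocyte markers had positive differences (median 1.34; 1 higher when adjusted over the list alone), with Cidea at 1.96 (SE 0.60), and the adjusted p was 4.83e-06. Macrophage markers had positive differences in 15 of 16 genes (median 0.20; 2 higher when adjusted over the list alone), with Cx3cr1 at 0.85 (SE 0.23) and an adjusted p of 4.36e-06. All 13 epicardial markers had negative differences, with a median of -0.51 and Lrrn4 at -0.73 (SE 0.25), and an adjusted p of 4.83e-07. Smooth muscle markers (median 0.55, Acta2 at 1.48, SE 0.50) had an adjusted p of 0.000289. Each of these 4 lists had adjusted p = 0.337 with an estimated correlation.

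Extracellular matrix genes (median 0.14) and circadian clock genes (median 0.25) were called with an adjusted p of 0.00152 and 0.0363, and adjusted p = 0.592 and 0.474 with an estimated correlation. Fry, which tests whether the genes of a list move one way, called 0 lists. Adipoq, an adipocyte hormone, had signals of 2181.9 or more in LA heterozygous replicates 1, 2 and 4 and of 611.4 or less in every other left atrial array. The smooth muscle gene Myh11 was high on the same arrays, with 328.8 or more against 112.9 or less in every other left atrial array. Without the 4 arrays with a Ucp1 signal over 100, which leaves 2 heterozygous LA arrays, 3 lists were called and the adipocyte list, to which Ucp1 belongs, had an adjusted p of 0.792.

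Without LA heterozygous replicate 3 or 4 or LA wild-type replicate 1, 3 or 5, the log2 difference of Cxcl13 was 1.74 or more, with adjusted p between 0.056 and 0.0856. Without the 4 arrays with Ucp1 over 100, which leaves 2 heterozygous LA arrays against 5, it was 1.57 (adjusted p = 0.655). The call of Cxcl13 was also lost with the replicate numbers as a fixed block, with no filter and with Myl2, Adipoq and Upk3b levels as covariates. It held in 18 of 27 other settings.

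**Figure D3:**
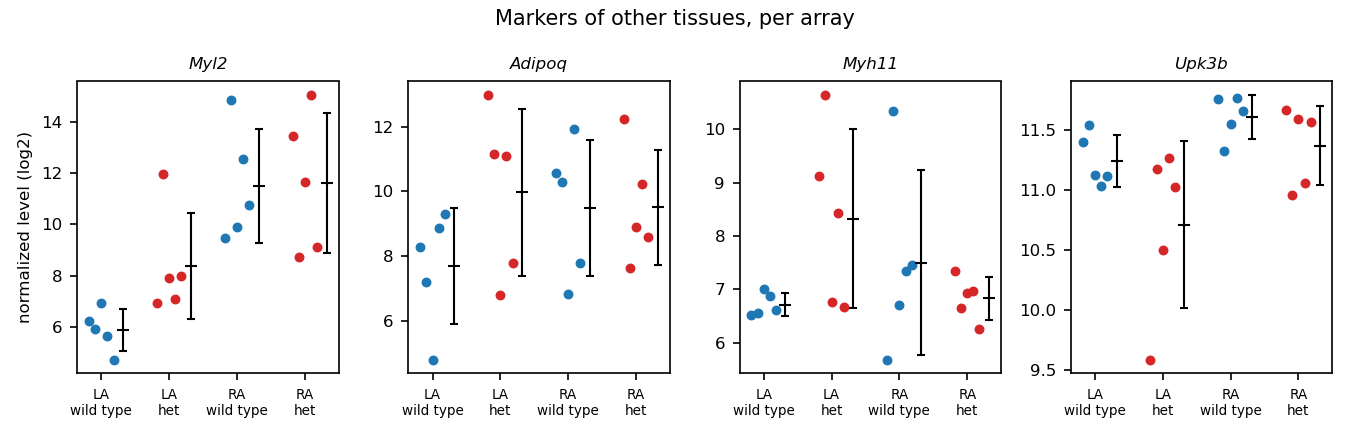
Normalized log2 level (y axis) of markers of ventricle (Myl2), fat (Adipoq), smooth muscle (Myh11) and epicardium (Upk3b) in each of the 20 arrays by atrium and genotype; points are arrays, bars the mean ± SD of 5 arrays, and y axes do not start at 0. Deposited Adipoq signals in heterozygous LA ran from 96.5 to 8120.3, those of Upk3b from 752.3 to 2447.4.

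The right atria of the genotypes were compared in the same way. No named gene passed. A pair of probes without a gene name passed, both higher in heterozygous mice. ILMN_3118071 was 13.1-fold higher, with a log2 difference of 3.71 (SE 0.17, n = 5 arrays per group, adjusted p = 3.3e-11 by limma). Its signals were between 435.1 and 835.1 in heterozygous RA, between 17.9 and 37.2 in wild-type RA and between 1134.5 and 1609.8 in LA of both genotypes. ILMN_1220244 was at least 3.42-fold higher (adjusted p = 3.1e-08), detected on 0 wild-type and all 5 heterozygous RA arrays. In LA the genotypes differed by -0.10 and -0.03 in these probes (adjusted p = 1 for each).

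Named genes with the smallest p in the right atrium had adjusted p of 0.818 or more. Chac1, a glutathione-degrading enzyme, had a log2 difference of 0.86, Ces1e 0.77, Tha1 0.50 and Ece2 0.47, and Kbtbd8, detected on 0 wild-type RA arrays, was at least 1.09-fold higher (adjusted p = 0.83). Cst9 had -0.97, Pcyt1b -0.40, the histone gene H3f3b -0.38 and Nelfa -0.34, and Efhd2, detected on 0 heterozygous RA arrays, was at least 1.24-fold lower (adjusted p = 0.83). Of the 13 fixed genes none passed, with differences between -0.87 for Bmp10 and 0.16 for Nkx2-5. Skeletal muscle markers were the 1 list called of 36, with positive differences in 9 of 10 genes and a median of 0.47; 0 members passed over all probes or when adjusted over the list alone. Among them were the parvalbumin gene Pvalb at 1.37 (SE 0.46) and Tnni2 at 1.22 (SE 0.45). The adjusted p was 0.0244, and adjusted p = 0.713 with an estimated correlation. At an unadjusted p under 0.05 there were 1087 probes.

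The number of lists called in the right atrium was 6 without RA wild-type replicate 1, and 6 without the 4 arrays with Ucp1 over 100. Myl2 signals over 10000 stood in RA heterozygous replicates 1 and 4 and RA wild-type replicate 2, and without these arrays 3 lists were called.

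The interaction asks whether the genotype difference is the same in both atria. It passed for the same pair of unnamed probes, whose genotype difference was lower in LA than in RA by a log2 value of -3.80 for ILMN_3118071 (adjusted p = 1.38e-08) and, for ILMN_1220244, by a value from -5.64 to -2.01 over 35 other settings (adjusted p = 1.11e-05), since it was detected on 0 wild-type RA arrays. No named gene passed over all probes. Those with the smallest p were Rprm (adjusted p = 0.915), Cxcl13 with 1.60, Arpp21, Vsig4 with 1.72, Treml1 with 0.71, Stom with -0.73, Cdh22 with -0.87, Gm11437 with -0.70, Dtx1 and Samd10 with -0.69, all but Rprm with an adjusted p of 0.999. No value is given for Rprm, Arpp21 and Dtx1, each detected on 0 arrays of at least 1 group. Arpp21 and Rprm each passed in 2 of 36 other settings, both without further background correction (adjusted p down to 0.000373 and 0.0486). These 2 settings use identical deposited values and are nearly the same fit, so they are not separate support. Among the 832 probes called between the sides, 2 passed over all probes and 4 when adjusted over them alone, the added ones being Rprm (adjusted p = 0.0379) and Cxcl13 (adjusted p = 0.0464). These 832 probes were chosen on the side differences that the interaction compares, so the narrower adjustment is not independent of it.

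By list, 9 were called in the interaction, 8 of them with a more positive genotype difference in LA than in RA, and 0 members passed. Adipocyte markers (median 1.47) and smooth muscle markers (median 0.79) had adjusted p = 1.63e-05 each, and adjusted p = 0.454 each with an estimated correlation. Over the 9 lists adjusted p = 0.415 or more with an estimated correlation, and 3 were called without the 4 arrays with Ucp1 over 100.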

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

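Chosen after the results were seen were the tests on Bmp10 as a mark of the side, on macrophage genes, on LA heterozygous replicate 2, on the arrays with Ucp1, and on the score of side genes in the left atrium.

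The pair of unnamed probes, ILMN_3118071 and ILMN_1220244, differed between genotypes in RA and not measurably in LA, with fitted interaction values of -3.80 and -2.30, the latter no exact difference (-5.64 to -2.01 over other settings), as ILMN_1220244 was detected on 0 wild-type RA arrays. Left atrial tissue in the heterozygous RA samples would have to supply a share of left signal between 0.361 and 0.379, but 18 other left genes gained a median share of 0.0536 (95% bootstrap interval 0.0064 to 0.102, 10000 resamples of the genes). The interval gives the spread between genes measured on the same arrays, not between mice. The low median share argues against left tissue as the whole cause. The stricter bound written beforehand, well under the needed share, was not met by the upper limit. The judgement against the needed share itself was made after the value was seen, and a small share stays open. Swapped sides are argued against by Bmp10, whose lowest right array lay 0.84 above the highest left array on the log2 scale. A genotype effect and a sequence variant carried with the allele in this outbred strain stay open, and neither was tested.

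In LA of heterozygous mice Cxcl13, Vsig4, Arpp21 and Cd207, all right atrial genes, had positive differences, and Rprm and Mapk10, left atrial genes, negative ones. Right atrial tissue would carry Bmp10 along, yet apart from replicate 2 the highest gain of Bmp10 was -0.000279 of its right atrial signal while the lowest gain of Cxcl13 was 0.0454. In LA heterozygous replicate 2 the gain of Bmp10 was 0.853 times that of Cxcl13. Cxcl13 gained a mean of 0.0616 on the other 4 arrays, where Bmp10 did not, so this ratio decides nothing. Bmp10 itself gained 0.0661 of its right atrial signal in replicate 2, so right atrial tissue may be present in that sample. More macrophages would raise the other macrophage genes too, and the median of 16 was 0.20 (interval 0.10 to 0.36 over resampled genes, not mice). That is a rise, though smaller than the 1.63 of Vsig4. The bound of 0.68 was derived from the brighter Cd207 probe (1.35), and a second Cd207 probe, with a difference of 0.67, would lower it. These values therefore do not decide whether more macrophages were present, which stays open. A score of 244 left and 303 right genes was lower by a log2 value of -0.17 in heterozygous LA (exact permutation p = 0.0714) and differed by 0.04 in RA (p = 0.651), which neither shows nor excludes a shift; for RA the reading written beforehand, that a p of 0.05 or more speaks against one, was dropped after the value was seen, since a p-value from 5 arrays per group bounds no effect size.

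In LA of heterozygous mice the adipocyte list was called higher and the epicardial list lower at the preset correlation. No member of either passed over all probes, and with an estimated correlation each list had an adjusted p of 0.337 (camera). Without the 4 arrays with a Ucp1 signal over 100 the adipocyte list had an adjusted p of 0.792, but Ucp1 is itself on that list and 2 heterozygous LA arrays remain, so this decides nothing about fat attached to some samples, which stays open. The epicardial list had an adjusted p of 1.08e-05 without these arrays at the preset correlation; on all arrays it had adjusted p = 0.337 with an estimated correlation, so whether less of the outer layer was present, in these or other samples, stays open too. How the appendages were trimmed is not given, and the markers of fat and outer layer are also expressed at some level in atrial tissue. Scgb1a1, from the list of lung epithelial markers, had signals of 173.2, 597.1 and 954.1 in LA wild-type replicates 1, 4 and 5. In RA wild-type replicates 3 and 4 it had 741.1 and 150.3, and on every heterozygous array 4.7 or less. Attached tissue may thus differ between the genotypes, which was not tested.

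Other splits of the same arrays, 100 drawn for each comparison with the real one included, gave the following. For probes in LA, 3 splits called as many as the real 1 (highest other 1); in RA, 4 called as many as the real 2 (highest other 1340); between sides, 1 reached 660 in wild type (highest other 12) and 1 reached 524 in heterozygotes (highest other 83); for the interaction, 2 reached 2 (highest other 35). No other split came near the real counts between the sides, which argues against chance for these if the arrays are exchangeable. The counts for LA, RA and the interaction were each reached by at least 1 other split. Their shares are under 0.05 but were not adjusted for the number of counts tested, so chance is not excluded for these counts. A split is scored by its count and not by which probes pass, so the shares do not weigh single probes. In RA the signals of ILMN_3118071 did not overlap between heterozygous (435.1 to 835.1) and wild-type mice (17.9 to 37.2). Those of ILMN_1220244 did not either (71.3 to 141.2 and -5.4 to 5.9). The arrays may not be exchangeable: both sides come from the same mice. With the replicate numbers as a fixed block LA had 0 probes. The split with 1340 sets RA heterozygous replicates 1 to 4 and RA wild-type replicate 1 against the rest, and so points to a structure of the samples: on RA heterozygous replicate 1 and RA wild-type replicate 1 the probes of a gene disagreed by a median of 0.258 and 0.240, on the other arrays by 0.130 to 0.213. For gene lists, 33 splits called as many as the real 6 in LA (highest other 10), 96 as many as the 1 in RA (15), 28 as many as the 8 between sides in wild type (13) and 16 as many as the 9 of the interaction (14), so chance cannot be excluded for these. For the 13 lists between sides in heterozygotes 3 splits called as many at the preset correlation (highest other 17). That share is likewise unadjusted and rests on exchangeable arrays, so chance is not excluded for this count either. Of the 13 lists, 1 was called with an estimated correlation.

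Among 420 groups of 5 arrays, for 105 genes and probes of the text, 25 held an array far from the other 4 by Dixon's ratio (over 0.71), where 21 would by chance. On LA heterozygous replicate 2 these were Bmp10 (0.956), Adm (0.952), Myl2 (0.794) and Msc (0.77), all high. On RA heterozygous replicate 1 they were ILMN_3118071 (0.903), Cidea (0.835), Id1 (0.817) and Dlgap1 (0.789), high, and H3f3b (0.773), low. On RA wild-type replicate 1 they were Gm11437 (0.896), high, and Dtx1 (0.886), Tbx3 (0.747) and Bmp10 (0.719), low. High were also Cxcl13 in LA wild-type replicate 4 (0.885), Cst9 in LA wild-type replicate 2 (0.729), Fcgr4 in LA wild-type replicate 3 (0.744), Vtn in RA wild-type replicate 2 (0.796), and Timp4 (0.715) and Mmrn1 (0.765) in RA heterozygous replicate 4. Low were Lonrf3 in LA heterozygous replicate 4 (0.956), Nelfa in LA heterozygous replicate 3 (0.737), Tnni2 (0.828) and Myl4 (0.756) in RA wild-type replicate 5, Col8a1 in RA heterozygous replicate 5 (0.828) and Gm11437 in LA wild-type replicate 3 (0.746).

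The lists called in the interaction were adipocyte, smooth muscle and extracellular matrix genes (adjusted p = 1.63e-05 each), macrophage markers (0.00203), cardiac transcription factors (0.0191), melanocyte genes and glycolysis (0.0267 each) and natriuretic and stress genes (0.0372), with positive medians, and epicardial markers (0.0103), with a median of -0.40. None was called with an estimated correlation.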

How the results depend on the processing

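Counts moved as follows, in the order LA genotype, RA genotype, sides in wild type, sides in heterozygotes and interaction, with 1, 2, 660, 524 and 2 probes and 6, 1, 8, 13 and 9 lists at the outset. Without further background correction, and alike with the second table of values, LA had 2 probes, the interaction 4, and RA 0 lists. With no filter LA had 0 probes (adjusted p of Cxcl13 0.0828, over its 27 settings 0.000526 to 0.655). With detection at 0.01 on all arrays LA, RA and the interaction had 0 probes, RA 2 lists and heterozygous sides 7. This filter left out Cxcl13, ILMN_3118071 and ILMN_1220244, which some arrays did not detect, so their calls were not tested there. Each of the unnamed pair passed in all 26 other settings that tested it in RA, and in all 35 for the interaction. With 1 probe per gene RA and the interaction had 0 probes, because unnamed probes are left out. Array weights gave 5 probes in LA, 1001 in wild-type sides and 2 lists in RA. Fits of the compared groups alone gave 322 probes in heterozygous sides and 3 lists in RA; Xist as a covariate gave 3 lists in RA and the mean of all probes of a gene 5. With an estimated correlation 0, 0, 2, 1 and 0 lists were called, and fry called 0 in LA and RA, 3 in heterozygous sides and 0 in the interaction. Same-numbered samples did not all deviate together (correlations from -0.42 to 0.35, best with the own number for 1 to 3 of 5 arrays), yet scores on the first within-group component followed the number between the genotypes (r = 0.908 in LA, exact p = 0.075, and 0.849 in RA, p = 0.0333, over 120 orders; chosen after the scores were seen), a hint of a shared structure that the labels do not explain; as a fixed block the numbers gave 0 probes in LA (Cxcl13 1.78, adjusted p = 0.0513), 337 in heterozygous sides and 4 lists in RA, and as a random block (correlation 0.0189) 682 and 549 probes between sides. Added after seeing the data: the signal floored at 0 plus 16 gave 2 probes in LA; without 3 arrays with Myl2 over 10000 there were 3 lists in RA, 8 in heterozygous sides and 5 in the interaction; without 4 arrays with Ucp1 over 100, which leaves 2 LA and 4 RA heterozygous arrays, there were 0 probes in LA and 250 in heterozygous sides, with 3 lists in LA, 6 in RA and 3 in the interaction; without the 2 arrays with disagreeing probes RA had 3 lists; Myl2, Adipoq and Upk3b as covariates gave 0 probes in LA, 351 and 207 between sides, and 4 lists in RA, 8 in heterozygous sides and 4 in the interaction. Leaving out 1 array gave 0 to 3 probes in LA, 2 to 2 in RA, 494 to 601 in wild-type sides, 356 to 525 in heterozygous sides and 2 to 2 in the interaction, and 5 to 9, 1 to 6, 7 to 10, 8 to 13 and 4 to 12 lists. LA had 0 probes without heterozygous replicate 3 or 4 or wild-type replicate 1, 3 or 5, 2 without heterozygous replicate 1 or 5 or wild-type replicate 2, and 3 without heterozygous replicate 2. RA lists were 6 without wild-type replicate 1, 5 without wild-type replicate 2, 4 without heterozygous replicate 1 or 3 or wild-type replicate 5, 3 without heterozygous replicate 5 or wild-type replicate 3, and 2 without heterozygous replicate 4. Heterozygous sides had 8 lists without RA heterozygous replicate 5, and the interaction 4 without RA heterozygous replicate 1. Of 5591 values for single genes under other settings 365 lost a call, 14 gained one, and 0 called values changed sign. The cause of these moves was not tested.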

Other observations

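Chosen after their values were seen were the genes of this part and the test of side genes in the left atrium.

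The genes of this paragraph were picked from those that passed between the sides in both genotypes, and no gene group was tested. Among immune genes (adjusted p between 0.00034 and 0.0351), higher in the left atrium were the lectin genes Clec10a (log2 difference 1.61 in wild type and 1.66 in heterozygotes) and Mgl2 (1.42 and 1.73) and the chemokine gene Ccl11 (1.43 and 1.75). Higher in the right atrium were the Fc receptor gene Fcgr4 (-1.56 and -1.26) and the lectin gene Clec7a (-1.28 and -0.95). Mmrn1 (2.12 and 1.21) and Reln (2.07 and 1.45), genes of lymphatic vessels, were higher on the left, as was Vtn (1.83 and 1.84). On the right were Igfbp3 (-2.31 and -2.13), Gng13 (-2.14 and -2.27), the transcription factor gene Msc (-1.99 and -1.85) and Fgf10 (-1.87 and -0.99).

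One hypothesis is that the loss of 1 copy of Pitx2c moves side genes of the left atrium a little toward the right, beyond Cxcl13. The score of side genes may carry this, with a difference of -0.17 and an exact permutation p of 0.0714, but it was -0.15 (p = 0.135) without the genes named for the pattern and -0.09 (p = 0.111) without LA heterozygous replicate 2, so it was not shown. Quantitative PCR of Cxcl13, Vsig4, Arpp21, Rprm and Mapk10 in left atria of new mice, with Bmp10 measured beside them, would test it.

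A further hypothesis is that the pair of unnamed probes reports a transcript whose level in RA depends on the allele or on a linked variant. Left tissue is argued against by the median share of 0.0536, but it may still add a small part. Aligning the probe sequences to the genome and genotyping the mice would separate these. Whether attached fat accounts for the adipocyte genes was not settled, and trimming recorded per sample would test that.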
